A study of Bos taurus with 18 samples.

How the data were processed

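RNA of 18 bovine demi-embryos was sequenced, 4 followed by pregnancy of the recipient and 14 not. Per the labels' protocols, total RNA was made into barcoded libraries with a low-input kit that depletes unwanted transcripts (NuGEN Ovation SoLo with a bovine AnyDeplete set) and sequenced single-end on an Illumina NextSeq. When a blastocyst was not cut evenly, the smaller or less intact part was the one sequenced, per the labels' protocols, so the amount of RNA can differ between libraries; it is not given in the sources used here. The labels disagree on origin and age: the series design speaks of embryos flushed from the uterus 8 days after the anticipated ovulation, the handling protocol of embryos on day 7 of culture. The series design was followed.

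The deposited values are whole-number counts per Ensembl gene ID, not normalized, 1 column per demi-embryo. Per the submitters' processing notes, the builds UMD3.1 and bosTau8 and the tool edgeR were used, with no role or version. The aligner, the counter, the strand setting, and the treatment of duplicate reads and of reads with several equal hits are not given in the sources used here. If copies of the same molecule were counted, counting error is understated. The file holds 24616 IDs, 1725 of them without a count, and no column of another series. It does not pair IDs with names, and 0 IDs matched the table of gene names used here. The gene lists, the rule for named genes and the covariates that need names, all fixed before the data were examined, were therefore not used. In place of that rule, the 2 IDs with the largest fold change in each direction were taken among those past the threshold whose 4 pregnant values lay on the same side of the not-pregnant median.

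The main comparison used edgeR 4.0.16 in R 4.3.3: filterByExpr by group (at least 10 counts at the median library size in 4 libraries, and 15 in total), TMM scaling, robust glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment and a threshold of 0.05. It tested 13060 IDs, which held 97.9% to 99.8% of each library's counts. The SE of a log2 fold change is the one implied by its F statistic. On simulated counts for this comparison, 200 of 13060 IDs were changed. Of these, 12.5% were recovered at 2-fold, 50.0% at 4-fold and 77.5% at 8-fold, with 0, 6 and 8 false calls. With no ID changed there were 0 calls. On the real counts, a split of 4 not-pregnant embryos against all others gave 50 higher and 134 lower IDs. Of the 100 splits drawn, 93 gave none. The simulated rate of false calls therefore need not hold for the real counts. Log2 CPM values used TMM and a prior count of 2. Library measures, the share of the squared distance between libraries taken by group (R2) and distances to the group centroid were compared by exact permutation over all 3060 choices of 4 of 18 embryos. Distances were corrected for group size.

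Before the data were examined, the following alternatives were chosen: RLE and upper quartile scaling, DESeq2 1.42.0, edgeR's likelihood ratio test, limma 3.58.1 with voom quality weights, 2 other filters, no robust fit, a block on the number in the titles, log2 total counts or 1 surrogate variable (sva 3.50.0) as covariate, thinned counts, not-pregnant 1 and 14 summed, and leaving out each library. Chosen after seeing the data were the abundance classes and the measures made from them, the TMM reference library, plain voom, quantile and cyclic loess normalization, the covariates for genes detected and for the sequencing index in the descriptions, near-identical IDs summed, the most abundant IDs left out, class medians without a filter, and 3 libraries left out together.

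Descriptions of not-pregnant 1 and 14 begin with the same number. Their counts differed by a chi-square of 24.0 per degree of freedom, against a median of 17.5 and a minimum of 4.00 over the 97 pairs within groups, so both were kept as separate samples. Total counts per library ran from 854791 to 4689576. No library or sequencing batch is labelled. Figures were drawn with matplotlib.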

Results

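The samples were 18 bovine demi-embryos. Blastocysts of superovulated Holstein heifers, flushed from the uterus 8 days after the anticipated ovulation per the series design, were cut in 2. One part went to RNA sequencing and the other was transferred to a recipient heifer, whose pregnancy was checked on days 30 and 60 of gestation. In 4 cases the recipient was pregnant at both checks (the pregnant group), and in 14 it was not pregnant on day 30 (the not-pregnant group). Each library is 1 part of 1 blastocyst, holding both trophectoderm, the outer layer that forms the placenta, and inner cell mass, which forms the fetus. The labels name no donor, so p-values measure the spread between embryos, some of which can share a donor. Total counts per library ran from 854791 to 2439701 in the pregnant group and from 1611847 to 4689576 in the not-pregnant group, with a median of 2084917 over all 18 libraries. The comparison asks whether the transcripts of an embryo differ between blastocysts whose transferred part did or did not establish a pregnancy.

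Between the groups, 45 gene IDs were higher and 56 were lower in embryos followed by pregnancy, out of 13060 tested, at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The higher IDs had a median log2 fold change of 1.80 and the lower IDs one of -1.07. The higher IDs were mostly of middle abundance, with a median of 13.3 CPM (counts scaled by the library total), and the lower IDs were mostly abundant, with a median of 231 CPM. For all 45 higher and all 56 lower IDs, the 4 pregnant values lay on the same side of the not-pregnant median. In 29 of the higher and 19 of the lower IDs, all 4 pregnant values lay outside the range of the 14 not-pregnant values. Over all tested IDs such a gap between the groups occurred in 1.58% of cases, against 0.0654% by chance. The file gives Ensembl gene IDs that are not paired with gene names, so only the 2 IDs furthest up and the 2 furthest down are given singly.

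ENSBTAG00000009438 had the largest rise, with a log2 fold change of 3.32 (SE 0.83, adjusted p = 0.0462 in edgeR). Its log2 CPM was 3.74 ± 0.51 (SD, n = 4) in the pregnant group and 0.88 ± 0.88 (SD, n = 14) in the not-pregnant group. It rested on 14 to 20 counts per pregnant library and 0 to 12 counts per not-pregnant library, 4 of which had none. ENSBTAG00000005697 rose by a log2 fold change of 3.21 (SE 0.80, adjusted p = 0.0462 in edgeR). Its log2 CPM was 3.76 ± 0.34 (SD, n = 4) against 0.94 ± 0.86 (SD, n = 14), from 9 to 22 counts per pregnant library and 0 to 11 per not-pregnant library.

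ENSBTAG00000000936 had the largest fall, with a log2 fold change of -3.89 (SE 0.70, adjusted p = 0.0158 in edgeR). Its log2 CPM was 0.93 ± 0.32 (SD, n = 4) in the pregnant group, where each library held 1 or 2 counts, and 3.82 ± 0.85 (SD, n = 14) in the not-pregnant group, with 7 to 77 counts per library. ENSBTAG00000001819 had a log2 fold change of -1.73 (SE 0.42, adjusted p = 0.0429 in edgeR), at 2.79 ± 0.50 (SD, n = 4) against 4.33 ± 0.57 log2 CPM (SD, n = 14). In each of these 4 IDs all pregnant libraries lay beyond all 14 not-pregnant libraries. Leaving out pregnant 1 ended the calls of all 4 IDs, at log2 fold changes of 3.34 (SE 0.94) and 3.03 (SE 0.94) for the risen IDs and -4.22 (SE 0.83) and -1.53 (SE 0.47) for the fallen ones. So did leaving out pregnant 3, the sequencing index as covariate and 1 surrogate variable, while ENSBTAG00000000936 alone stayed called without pregnant 2, without pregnant 5 and with log2 total counts as covariate. A covariate for genes detected at equal depth also ended all 4 calls, with the risen IDs at 1.08 (SE 1.77) and 1.48 (SE 1.37) and the fallen ones at -4.32 (SE 0.86) and -1.51 (SE 0.57). None of the 4 was called in limma voom after cyclic loess. The risen IDs were then at 1.97 (SE 0.78) and 2.05 (SE 0.73) and the fallen ones at -3.64 (SE 1.01) and -1.81 (SE 0.57).

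**Figure D1:**
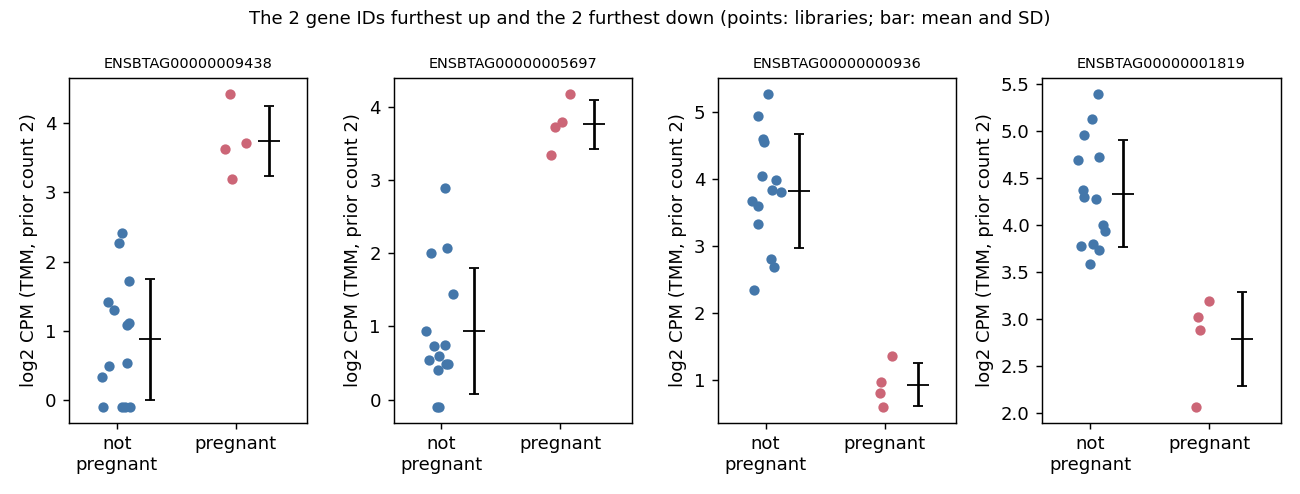
Expression of the 2 gene IDs furthest up and the 2 furthest down, in log2 CPM after TMM scaling with a prior count of 2, for the 14 not-pregnant libraries (blue) and the 4 pregnant libraries (red). Points are libraries and bars show the mean and SD; in each ID the 4 pregnant libraries lie outside the not-pregnant range.

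The counts of called IDs depended on most single libraries and on the scaling. Without pregnant 1, edgeR called 0 higher and 0 lower IDs, with 977 and 746 at an unadjusted p under 0.05. Without pregnant 2 the counts were 4 and 9, without pregnant 3 they were 1 and 2, and without pregnant 5 they were 2 and 12. Leaving out single not-pregnant libraries gave 26 to 92 higher and 36 to 272 lower IDs; among them, without not-pregnant 5 there were 26 and 39, without not-pregnant 10 there were 78 and 272, and without not-pregnant 16 there were 92 and 267. In the last 2 cases the TMM reference also changed, from not-pregnant 11 to 15, which alone gave 63 and 189, and without pregnant 3 it changed to not-pregnant 3. For the 45 higher IDs the median log2 fold change without pregnant 1 was 1.75, and for the 56 lower IDs -1.04. All kept their sign, while their median SE went from 0.41 to 0.47 and from 0.24 to 0.28. These IDs were chosen by a fit that held the remaining libraries too. That their signs and medians changed little is partly given by this choice. The TMM method scales every library to 1 reference library, by default not-pregnant 11, the library with the highest total and the fewest genes detected. With each of the other 17 libraries as reference, 47 to 66 IDs were higher and 151 to 217 were lower, so that higher IDs made up 20.2% to 28.2% of the calls in place of 44.6%. The median log2 fold change over all tested IDs moved from 0.10 to between -0.01 and 0.03. The test also changed the counts: limma voom with TMM called 933 higher and 153 lower IDs (85.9% higher). Against that, limma voom called 175 higher and 14 lower after quantile normalization (92.6% higher), and 11 and 0 after cyclic loess (414 lower at an unadjusted p under 0.05). With log2 total counts as a covariate 0 higher and 1 lower ID passed in edgeR (373 and 469 at an unadjusted p under 0.05), with medians of 1.51 (median SE 0.52) and -0.91 (median SE 0.31) for the 45 and 56 IDs. With genes detected at equal depth as a covariate 0 and 0 passed (144 and 347 at an unadjusted p under 0.05).

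**Figure D2:**
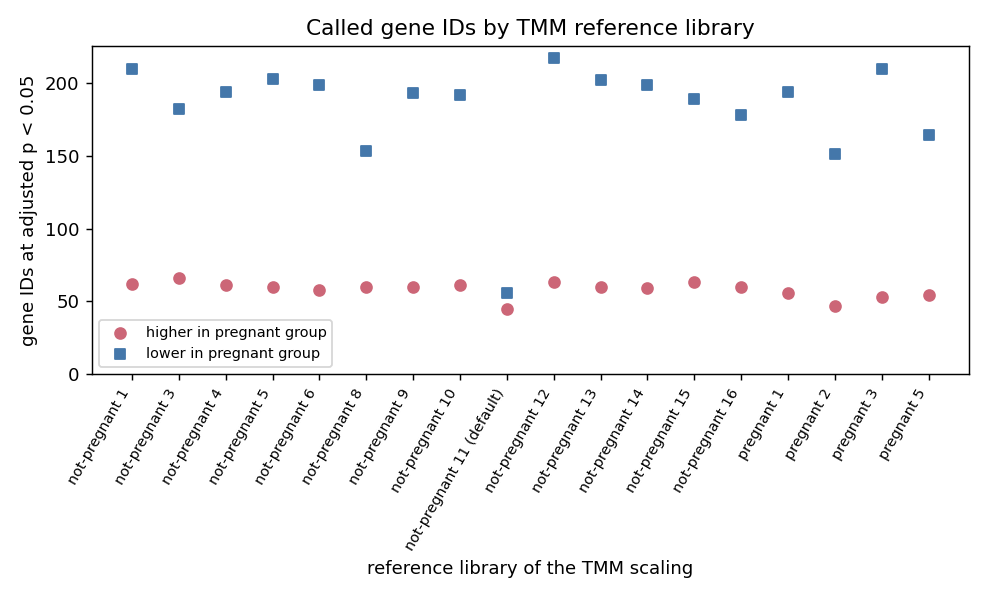
Number of gene IDs called higher (red circles) and lower (blue squares) in the pregnant group at an adjusted p under 0.05 in edgeR, by the library used as TMM reference. The default reference, not-pregnant 11, gave 45 and 56, and the other 17 gave 47 to 66 and 151 to 217.

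Fold changes followed abundance. IDs of low abundance (mean under 4 CPM, 1764 tested) had a median log2 fold change of 1.03, and 85.8% of them were above 0. The filter keeps an ID of this class mainly where about 4 libraries are high, so these are a selected part of the class. Over all 11591 low-abundance IDs, in a fit without a filter chosen after seeing the data, the median was 0.79 with 71.0% above 0, against 0.08 in the middle and -0.34 in the high class. IDs of middle abundance (4 to under 32 CPM, 7396 tested) had a median of 0.23, with 41 called higher and 3 called lower. IDs of high abundance (32 CPM or more, 3900 tested) had a median of -0.19, with 3 called higher and 53 called lower. Without pregnant 3 the medians of the low, middle and high classes were 0.94, 0.14 and -0.32, and with not-pregnant 15 as TMM reference 0.95, 0.15 and -0.27. In the low class 1 ID was called higher and 0 lower in edgeR, with 199 and 5 at an unadjusted p under 0.05. In limma voom with TMM the medians of the low, middle and high classes were 1.76, 0.34 and -0.18. The low-class median was thus larger than the 1.03 in edgeR, and whether the smaller pregnant totals add to it was not tested. In the same test after cyclic loess, which removes a trend with abundance by construction, they were -0.10, 0.05 and 0.01, and after quantile normalization 0.36, -0.06 and -0.04.

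**Figure D3:**
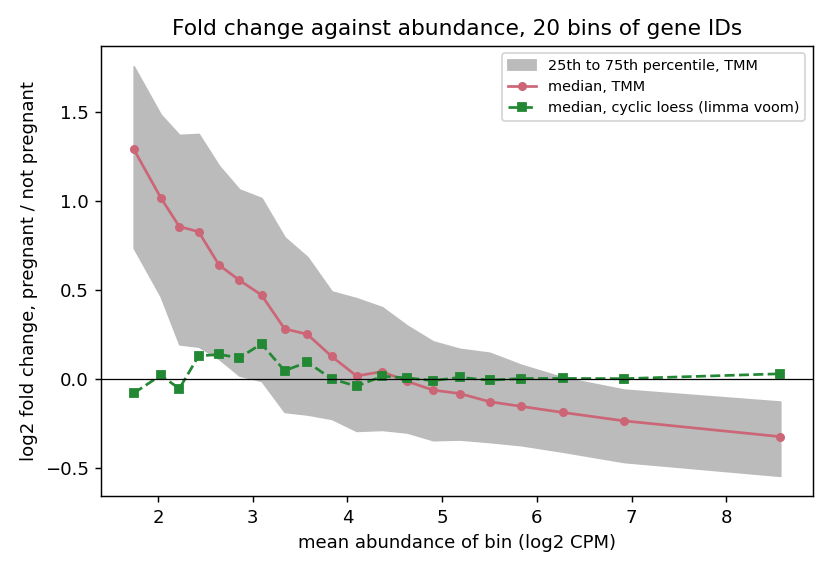
Median log2 fold change (pregnant over not pregnant) in 20 equal bins of tested gene IDs, against the mean log2 CPM of the bin; the lowest bins hold IDs selected by the filter. The red line and the grey band (25th to 75th percentile) are from the edgeR fit with TMM, and the green dashed line is from limma voom after cyclic loess; the red line falls with abundance and the green line stays near 0.

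The composition of the libraries showed the same pattern in pregnant 1, 2 and 5, and in pregnant 3 for the low class alone. IDs of low abundance, 11591 in the file, took 2.76% ± 0.60 of the counts (SD, n = 4) in the pregnant group and 1.28% ± 0.33 (SD, n = 14) in the not-pregnant group. All 4 pregnant libraries lay above all 14 others (exact two-sided permutation p = 0.000327, the smallest that the 3060 choices of 4 of 18 embryos can give; adjusted over 7 measures, 0.00114). Log2 counts in these low-abundance IDs differed by 0.24 between the groups and did not pass (exact permutation p = 0.135). Smaller totals in the pregnant group thus made up much of its larger share. IDs of middle abundance took 11.4% ± 2.61 against 9.23% ± 0.76 (exact permutation p = 0.0134, adjusted 0.0188), with 3 pregnant libraries above all others and pregnant 3 below all of them. Leaving out pregnant 1, 2 or 5 took that exact permutation p to 0.0559, 0.0544 and 0.0544, and leaving out pregnant 3 took the difference from 2.16 to 3.43 points (exact permutation p = 0.00147). With the lower limit of the middle class set at 8 CPM in place of 4, the difference was 1.22 points and did not pass (exact permutation p = 0.0650), and at 2 CPM it was 2.99 points (exact permutation p = 0.00458), while the low share passed at both. IDs of high abundance took 85.9% ± 3.21 against 89.5% ± 0.94 (exact permutation p = 0.00458, adjusted 0.00801), with pregnant 3, at 90.7%, inside the not-pregnant range of 87.2% to 91.5%. The 20 most abundant IDs took 42.5% ± 10.9 against 37.2% ± 6.53, a difference within the spread between embryos (exact permutation p = 0.224). In pregnant 3 they took 58.8%. Among the counts outside those 20 IDs, the low class took 4.78% ± 0.20 (SD, n = 4) against 2.08% ± 0.66 (SD, n = 14), the middle class 19.7% ± 1.04 against 14.8% ± 1.17, and the high class 75.6% ± 1.24 against 83.2% ± 1.80. In each of these 3 shares the groups did not overlap (exact permutation p = 0.000327). The split without the 20 IDs was chosen after seeing the data, as were the class limits.

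**Figure D4:**
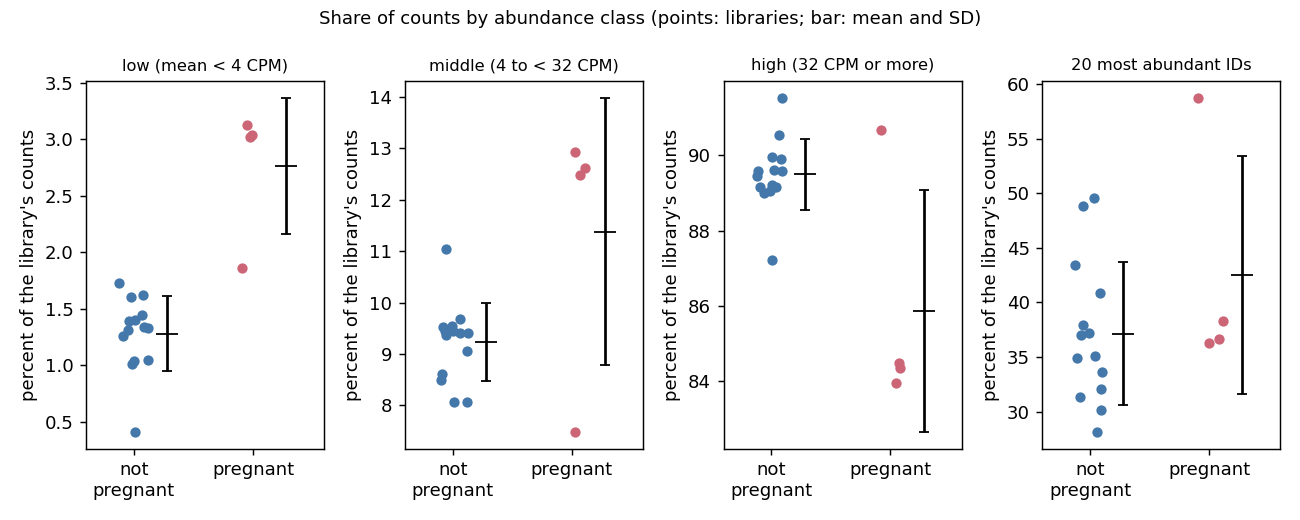
Percent of each library's counts in gene IDs of low, middle and high mean abundance and in the 20 most abundant IDs, for 14 not-pregnant (blue) and 4 pregnant (red) libraries, with the mean and SD as bars; the vertical axes do not start at 0. The low-abundance share of every pregnant library is above that of every not-pregnant library, and pregnant 3 lies apart from the other pregnant libraries in all 4 panels.

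More gene IDs were detected in the pregnant group although its libraries were smaller. At 1 or more counts, 18517 ± 434 IDs (SD, n = 4) were detected in the pregnant group and 16659 ± 1091 (SD, n = 14) in the not-pregnant group, with all 4 above all 14 (exact two-sided permutation p = 0.00229, adjusted 0.00534). With every library thinned at random to 854791 counts, the means were 17670 ± 1042 and 14682 ± 1184, again with no overlap (exact permutation p = 0.000327, adjusted 0.00114). At 5 or more counts the difference was 738 IDs without thinning (exact permutation p = 0.0621) and 2166 IDs with thinned counts (exact permutation p = 0.00098), the latter chosen after seeing the data. Log2 total counts differed by -0.90 between the group means, pregnant minus not pregnant (exact two-sided permutation p = 0.00523), with 3 of the 4 pregnant libraries below all 14 others.

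**Figure D5:**
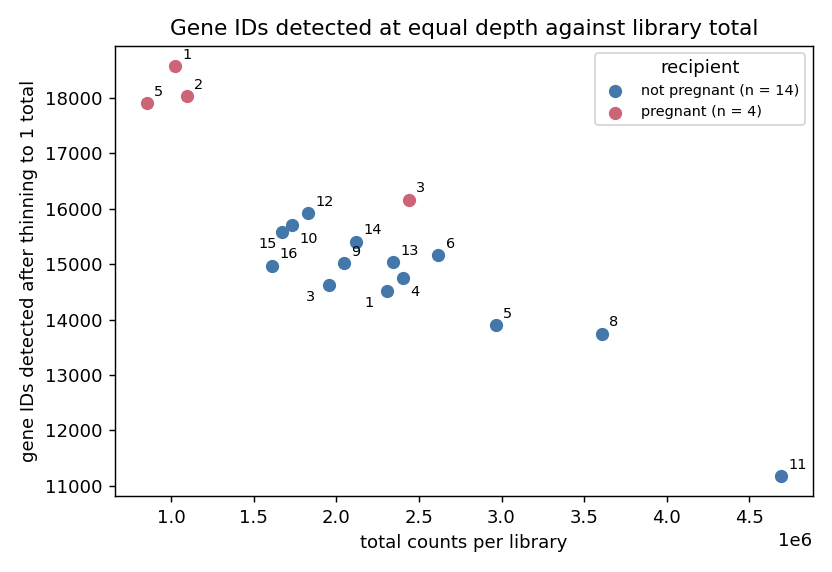
Gene IDs detected after thinning every library to 854791 counts, against the library's total counts before thinning, with the replicate number beside each point. The 4 pregnant libraries (red) hold 16168 to 18570 IDs and the 14 not-pregnant libraries (blue) 11183 to 15919.

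Over all tested IDs the groups differed as a whole. Group took 15.5% of the squared distance between libraries (R2 = 0.155, exact permutation p of the distances = 0.000327). The first principal component held 21.7% of the variance, and on it all 4 pregnant libraries (57.6 to 71.5) lay above all 14 not-pregnant libraries (-92.1 to 27.1). With IDs of 32 CPM or more alone, R2 was 0.122 (exact permutation p = 0.00588). Embryos of the pregnant group lay 84.9 ± 7.97 (SD, n = 4) from the centroid of their group and those of the not-pregnant group 95.2 ± 9.85 (SD, n = 14), in units of log2 CPM over all tested IDs. That difference did not pass the threshold (exact two-sided permutation p = 0.0758). The difference of -10.3 became -13.2 with thinned counts (exact permutation p = 0.0167), -5.08 without pregnant 1 (exact permutation p = 0.407) and -1.36 with IDs of 32 CPM or more (exact permutation p = 0.564).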

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

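The outlier test was set before the data were examined and some of its measures after, while both tests of explanations in this part were chosen after the result was seen. Of 17 measures looked at in the 4 pregnant libraries, 6 set pregnant 3 apart from the other 3 by a gap that is large against the range of the group; chance does this in about 1 of 20 groups, and the 6 measures are not independent. Pregnant 3 had 2439701 counts, against 854791 to 1095874 in the other 3. Its low-abundance IDs took 1.86% of the counts (others 3.02% to 3.13%), its middle class 7.48% (others 12.5% to 12.9%) and its high class 90.7% (others 83.9% to 84.5%). The 20 most abundant IDs took 58.8% (others 36.2% to 38.3%), and the rest of the high class 31.9% (others 46.1% to 48.1%).

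Whether pregnant 3 has a wrong group label cannot be told here. Its low-abundance share among counts outside the 20 most abundant IDs was 4.51%, against at most 3.22% in the 14 not-pregnant libraries. That speaks against a wrong label only if this share follows outcome and not RNA amount or library making, which is not known. A few IDs taking most of the counts is a candidate explanation for its class shares. With those 20 IDs left out, no class share of pregnant 3 passed the outlier test, and the largest gap was 0.731 of the group's range. Pregnant 3 was still the outermost pregnant library in each share, with a middle class of 18.1% (others 19.8% to 20.4%). With 4 libraries the test cannot show that a gap is absent. Leaving out the 20 IDs does not bear on its higher total. Whether they were raised in the embryo or in the library was not tested.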

How the results depend on the processing

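The TMM reference, plain voom, quantile and cyclic loess normalization, IDs or 3 libraries left out together, near-identical IDs summed, IDs of 32 CPM or more, and the covariates for genes detected and sequencing index were chosen after seeing the data. Counts of IDs higher and lower (45 and 56) stayed within 1.5 times with RLE (41 and 42), upper quartile scaling (44 and 39) and no robust fit (32 and 39). Other tests gave more: DESeq2 149 and 179, edgeR's likelihood ratio test 956 and 449, voom with quality weights 1807 and 461, plain voom 933 and 153. Without a filter there were 282 and 341, and with CPM above 1 in at least 4 libraries 85 and 321. In limma voom, quantile normalization gave 175 and 14 (median log2 fold changes of the IDs called in the main test 1.83, SE 0.39, and -0.73, SE 0.23) and cyclic loess 11 and 0 (1.72, SE 0.44, and -0.76, SE 0.24). IDs of 32 CPM or more gave 1 and 0, with 3 of the higher IDs tested and the lower ones at -0.87 (SE 0.23). Log2 total counts as covariate gave 0 and 1, 1 surrogate variable 0 and 0 (227 and 315 at an unadjusted p under 0.05; medians 1.21, SE 0.62, and -0.56, SE 0.26), genes detected 0 and 0, and the sequencing index 1 and 0 (medians 104% and 93.5% of those without it, SE 0.45 and 0.25). Thinned counts gave 26 and 40, and 10 further thinnings 2 to 14 and 11 to 31, so this value varies with the draw. Not-pregnant 1 and 14 summed gave 69 and 72. The TMM reference not-pregnant 15 gave 63 and 189, and no other of the 100 splits reached this (highest 52 and 112). The reference also changed away from not-pregnant 11 with near-identical IDs summed (63 and 174), with the 20 most abundant IDs left out (61 and 214), and without not-pregnant 10 (78 and 272), 11 (89 and 153), 12 (44 and 130), 16 (92 and 267) or pregnant 3 (1 and 2). Without not-pregnant 11, 16 and pregnant 3 together there were 65 and 134. Leaving out each library gave 0 to 92 higher and 0 to 272 lower IDs. With not-pregnant 11 still the reference, leaving out not-pregnant 13 gave 73 and 108, not-pregnant 14 66 and 65, and not-pregnant 1, 3, 4, 5, 6, 8 or 15 gave 26 to 29 and 36 to 50; the cause was not tested.

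Title numbers do not pair samples: the 3 shared ones had correlations of deviations of -0.04, 0.07 and -0.03, none correlating best with its own. Only these 3 bear on group in the replicate block, so its 343 and 248 are no check. The 4 named IDs kept their direction in every alternative that tested them; thinned counts did not test the 2 risen IDs, and the limit of 32 CPM tested none of the 4. They had adjusted p from 3.86e-05 to 1.00 (ENSBTAG00000009438), 3.08e-06 to 1.00 (ENSBTAG00000005697), 2.39e-05 to 0.504 (ENSBTAG00000000936) and 0.00232 to 1.00 (ENSBTAG00000001819).

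Leaving out each library, the differences kept direction and side of the threshold for log2 totals (-1.23 to -0.72), genes detected (1595 to 2061), R2 (0.137 to 0.167) and the low-abundance share (1.35 to 1.80 points). Genes with 5 or more counts differed by 738 and did not pass, and by 2166 and passed with thinned counts, chosen after seeing the data. The difference in spread ran from -15.0 to -5.08 and passed with prior count 0.5 (-21.8), the 500 most variable genes (-4.79), thinned counts (-13.2) and without not-pregnant 15 (-11.3), 16 (-9.36) or pregnant 3 (-15.0), but was -1.36 with IDs of 32 CPM or more; the cause was not tested. Gene lists, their scores and covariates that need gene names were not run. No library was left out as too small.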

Other observations

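The comparison of genes detected was planned before the data were examined, and the other tests in this part were chosen after the results were seen. Some IDs had similar counts in every library. Among IDs with 2000 or more counts, 19 IDs formed 6 sets whose members had totals within 10% and log2 counts correlated above 0.99 over the 18 libraries. The most abundant set held 4 IDs, all 4 among the 56 called lower. Together they took 0.684% ± 0.10 of the counts in the pregnant group (SD, n = 4) and 1.82% ± 0.72 in the not-pregnant group (SD, n = 14), a log2 difference of -1.32 (exact two-sided permutation p = 0.000654). Because such IDs can share reads, these 4 calls count as 1 at most, and their single values are uncertain. The other 5 sets held no called ID. In 1 of these, with 2 IDs, the counts differed by a chi-square of 35.7 per degree of freedom. The median was 15.3 for pairs of IDs outside the sets, but chi-square grows with counts and totals were not matched. These 2 IDs, with 326206 counts, thus differed beyond counting error, but the value does not tell by how much.

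Among the 14 not-pregnant embryos, larger libraries held fewer genes at equal depth. Log2 total counts and genes detected after thinning had Pearson r = -0.87 (permutation p = 8e-05, adjusted over 3 relations 0.00024) and Spearman rho = -0.67 (permutation p = 0.011, adjusted 0.033), with r = -0.66 without the 2 libraries farthest from the median total. The sequencing index had r = 0.04 (permutation p = 0.89, adjusted 0.91) and rho = 0.02 (permutation p = 0.96, adjusted 0.96) with genes detected, and r = 0.12 without the 2 farthest. Pregnant 1, 2 and 5 had indexes of 5, 2 and 23, outside the not-pregnant range of 6 to 22, and pregnant 3 had 9. The relation among not-pregnant libraries therefore cannot show that the index has no part in the group difference. Log2 total counts and log2 counts in low-abundance IDs had r = -0.03 (permutation p = 0.91, adjusted 0.91) and rho = 0.35 (permutation p = 0.22, adjusted 0.33), but r = 0.56 without the 2 farthest, so that this relation rests on those libraries.

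More genes and a larger low-abundance share were found in the pregnant group. Sampling depth is argued against, since it would give the smaller pregnant libraries fewer genes, and they had 1859 more before thinning (exact permutation p = 0.00229); whatever makes larger not-pregnant libraries hold fewer genes at equal depth stays open, and 3 of the 4 pregnant totals lie outside the not-pregnant range. Repeated copies of few molecules stay open too: more of them in the not-pregnant group would lower its genes detected at equal depth, and the low-abundance share, 2.16 times as large in the pregnant group, goes against them only if copying was uniform, which no value here measures. A background of fixed amount, such as stray RNA or DNA, could take a larger share where an embryo gave less RNA. Among not-pregnant libraries the slope of log2 low-abundance counts on log2 total was -0.0434 (95% bootstrap interval -0.40 to 0.53). For this slope the low class was cut on the not-pregnant libraries alone. A slope of 0 means fixed and 1 proportional only if totals follow the amount of RNA, which is not known. Without not-pregnant 11 the slope was 0.39 (0.13 to 0.62), between both. This explanation cannot be told apart from a difference between embryos that did and did not lead to pregnancy, which was not tested, because RNA amounts are not in the labels.

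For the called IDs, chance is argued against, with 1 larger split among those drawn: of 100 splits of the 18 libraries, the real one included, 2 gave as many higher IDs (45, highest other 50) and 2 as many lower (56, highest other 134), the other split in both cases being not-pregnant 1, 4, 5 and 12 against the rest. The TMM reference is argued against as the source of the higher calls. At least 44 of these 45 IDs were called with each of the 17 other references. All 56 lower IDs were also called, but those references moved the median log2 fold change from 0.10 to between -0.01 and 0.03. That favours lower calls, so it does not decide for the lower IDs. Of the called IDs, RLE kept 40 higher and 42 lower, and upper quartile scaling 43 and 39. In limma voom, TMM kept 45 and 54, quantile normalization 40 and 9, and cyclic loess 7 and 0. Genes detected per library are a candidate explanation for the higher IDs: among not-pregnant embryos alone, 95.6% of them rose with genes detected (permutation p = 0.014), or 82.2% without not-pregnant 11, and with that covariate their median log2 fold change went from 1.80 (median SE 0.41) to 0.95 (0.62), so the calls ended through both a smaller fold and a larger error. The share of uncalled IDs of like abundance that rose with genes detected is not given here. The rise therefore need not be particular to these 45 IDs. For the lower IDs, genes detected cannot be told apart from the group. Of them 87.5% fell with genes detected (permutation p = 0.076), or 76.8% without not-pregnant 11, and the median moved from -1.07 (0.24) to -0.81 (0.36). The groups do not overlap in genes detected, and a difference between embryos by outcome stays open and untested.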
